A study of Mus musculus with 2 samples.

How the data were processed

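RNA of degenerative and normal mouse cornea was compared on 2 hybridisations of a 2-colour array that carried 37632 spots in 48 print blocks. Per the labels, the mice were of the BALB/c strain, both corneas came from unilaterally affected animals, and RNA was extracted with Trizol, purified on columns, amplified and labelled with a CapitalBio kit. The degenerative sample carried Cy5 on array 1 and Cy3 on array 2, and the titles, the dye fields of the labels and the file headers all gave this orientation. The labels name no separate animals or pools. The arrays were therefore taken as 1 technical dye swap of the same pair of RNA extracts and counted as 1 replicate. No p-value, standard error or test across genes was computed. Each SD given beside a log2 ratio is between the 2 arrays and covers technical error only, and the number of arrays limits the precision.

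The deposited files hold, for each spot, a Cy5 and a Cy3 intensity on a linear scale. These deposited intensities include values below 0, so a background had already been subtracted; the scanner, the software and the background method are not given in the sources used here. The files also hold the authors' normalized log2 ratio, which per the file headers is Cy5 over Cy3 on array 1 and Cy3 over Cy5 on array 2, and thus degenerative over normal on both. The linear form of this ratio, also deposited, was not used for any result. The authors' normalization method is not given in the sources used here. The value table of the series equals the deposited log2 ratios, with a largest difference of 0, and was used as an alternative source of values. Its column medians over the measured probes were -0.00 and -0.03, so it is centred near 0. The deposited linear column equals 2 to the power of this ratio, which gives the log2 scale, and the direction was read from the file headers and titles.

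Because the intensities were already corrected, background correction on foreground and background signals was not possible. This departed from the first form of the design and followed its second form for corrected signals. For each channel, the 95th percentile of 728 blank and empty spots served as the background threshold. It was 1000.4 for Cy5 and 1216 for Cy3 on array 1, and 1238 for Cy5 and 1824 for Cy3 on array 2. Pooling blank with empty spots was decided after the intensities of control spots had been seen and before any ratio had been computed. Intensities below the threshold were raised to it. A probe was kept when at least 1 of the 2 RNAs exceeded the threshold on both arrays. Log2 ratios were then normalized within each array by loess (span 0.3), fitted on gene probes above the threshold in both channels, with limma 3.58.1 in R 4.3.3. The 1780 control spots were left out of all results. A spot was called saturated at 99% or more of the highest intensity in its channel.

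A gene not above the threshold in a sample on either array has only a bound there, and its fold is given as at least that size, taken against the threshold after loess normalization, as the mean of both arrays. Names came from the files and were matched to current symbols through a gene table of assembly GRCm38.p6, used for names only. Of 35852 gene probes, 17862 had a name; 11366 matched a current symbol, 2660 an older symbol, 100 were ambiguous and 3736 had no match and kept the file's name. The remaining 17990 probes were unnamed. A gene with several kept probes took the brightest. Of 421 such genes, 140 had probes that differed in sign.

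The groups, the alternatives, the rule for named genes and 35 gene lists with 687 entries (667 distinct genes) were fixed before the data were examined. A probe or gene was counted as higher or lower when its log2 ratio was at least 1, or at most -1, on both arrays. Probes that reached this size with opposite signs were counted beside it as the technical error count. Named were the 12 genes with the highest and the 12 with the lowest mean log2 ratio among those that passed, leaving out predicted or unnamed models, up to 4 members of each list with the largest absolute ratio, and Krt12, Kera, Mmp9, Vegfa, Spp1, Actb and Gapdh. Of the genes this rule takes, some are included in the counts and list medians but are not reported here by name. Each list with at least 3 measured genes was summarised by its median log2 ratio and set against 10000 random lists of the same size, matched on intensity in 20 bins. The interval that held the central 95% of the random medians describes these arrays and is not a test; its use as a marker of lists that stood apart was chosen after the design was fixed.

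The alternatives were median centring without loess, print-tip loess (span 0.4), no filter on dim probes, the brighter part of all probes by mean intensity, the authors' deposited ratios, each array alone, Aquantile scaling between arrays, the mean of all probes of a gene, other size rules, the mean of a list and unmatched random lists. Chosen after seeing the data were a threshold from blank spots alone, a threshold that included spots named DMSO, normexp with offset 50 in place of the raised floor, and lists without saturated genes. An analysis of signals without background subtraction was not run. Lists were analysed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

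The steps were tested on simulated data. On 8563 simulated probes with 50 changed at each size, the 2-fold rule called 18% of those changed by a log2 ratio of 1, 96% at 1.5, 96% at 2 and 100% at 3. It called 0 in the wrong direction and 0 unchanged probes. The simulated noise was Gaussian with an SD of 0.13 on 1 array, so an unchanged probe could hardly reach 2-fold on both. That 0 therefore says little about errors on the real arrays. Changed probes were drawn from those above the threshold in every channel, so the rates do not cover dim or floored probes. The mean estimate at a log2 ratio of 3 was 2.64, and the cause of the shortfall was not tested. Of 200 simulated lists of 12 genes without a shift, 10 (5%) lay outside the random interval, and of 100 lists shifted by 0.5 all 100 did. Each gene's value was drawn independently, so the 5% checks the procedure alone and not lists of genes that vary together. The shift of 0.5 exceeds the medians of 0.18 for corneal epithelium and proliferation and 0.15 for interferon response. Whether shifts that small would be found was not tested.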

Results

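Gene expression was measured in degenerative corneas and in normal corneas of the same unilaterally affected BALB/c mice, an albino inbred strain. Per the labels, the degeneration was spontaneous. A pair of 2-colour arrays with opposite dye orientation carried 35852 gene probes each. Median gene probe intensity was 246 in Cy5 and 439 in Cy3 on array 1, and 226 and 413 on array 2. Most probes were dim: 8656 (24.1%) exceeded background for at least 1 of the 2 RNAs on both arrays. They represented 5000 named genes, 704 of them predicted or unnamed models, and 3152 of the probes had no name. The comparison asked which genes differ between the degenerative and the normal cornea. With 1 technical pair of arrays there was no biological replicate, and every ratio below is the mean of the 2 arrays with the SD between them.

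Genes of lens and retina were among those that differed most. Lens crystallins were up to 5.49-fold higher in the degenerative sample, and rod photoreceptor genes were up to 4.29-fold lower. Beside the crystallins, the keratin Krt16 and the acute-phase genes Saa1 and Saa3 were at least 2-fold higher, Saa3 by an amount with a lower bound alone. Genes of the corneal epithelium and of proliferation were higher as groups by small amounts. So were those of fibrotic matrix and of the interferon response, but these lists fell inside their random intervals under some of the alternatives given below. An unequal share of other eye tissue could contribute to these small shifts, and this was not settled. In all, 17 probes (15 genes) were at least 2-fold higher on both arrays and 22 probes (20 genes) at least 2-fold lower, against 0 probes that reached 2-fold with opposite signs. Of the 5000 genes, 4816 (96.3%) lay within 1.5-fold on both arrays. The authors' deposited ratios gave 18 probes higher and 45 lower under the same rule.

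The log2 ratios of the 2 arrays, both turned to degenerative over normal, had a Pearson correlation of 0.668 and a Spearman correlation of 0.562 across the 8656 kept probes. Before turning, the Pearson value was -0.668, the sign that opposite dye orientations require. Probes are not independent replicates, and no p-value was attached. The median SD between arrays was 0.0929 on the log2 scale, and 95% of genes had an SD at or below 0.295. Without the filter on dim probes, the deposited ratios had a correlation of -0.0285, with 979 probes at 2-fold in the same direction and 1177 in opposite directions.

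**Figure D1:**
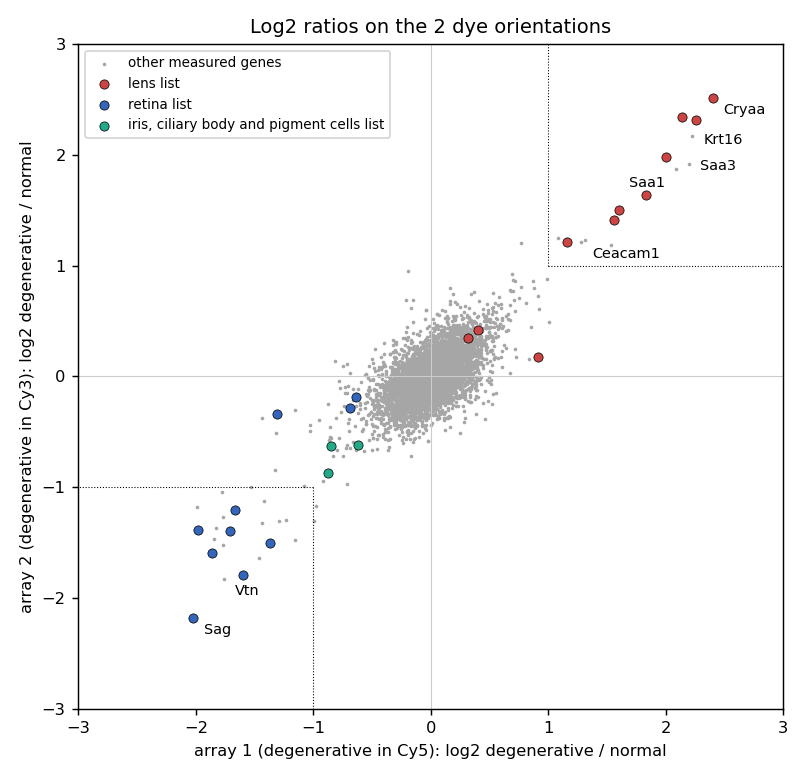
Log2 ratio of degenerative over normal on array 1 (horizontal) and array 2 (vertical) for the 5000 measured genes, each point a gene; dotted lines mark 2-fold on both arrays. Lens genes lie at the upper right, led by Cryaa at 2.40 and 2.51, and retina genes at the lower left, led by Sag at -2.02 and -2.18.

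Lens crystallins, the structural proteins of lens fibres, made up 10 of the 14 named genes at least 2-fold higher. Cryaa, an alpha-crystallin with chaperone activity, had a log2 ratio of 2.46 ± 0.08 (5.49-fold). Crygs reached 2.29 ± 0.04 (4.88-fold), Cryba1 2.24 ± 0.14 (4.72-fold) and Crybb2 1.99 ± 0.02 (3.97-fold). The others were Cryba2 at 1.73 ± 0.14, Crygc at 1.55 ± 0.07, Crygd at 1.48 ± 0.11, Crygf at 1.36 ± 0.25, Cryge at 1.27 ± 0.06 and Crybb3 at 1.18 ± 0.04. Of the fixed lens list, 11 of 19 genes were measured, all 11 were above 0 on both arrays and 8 were at least 2-fold higher. The filter and the floor largely set the sign of Crybb1, whose normal signal was not well above background. The list median was 1.55, against -0.13 to 0.16 for the central 95% of random lists. Cryab, an alpha-crystallin also made outside the lens, was at 0.33 ± 0.02, with probes that differed in sign, and Mip, the water channel of lens fibres, at 0.41 ± 0.01. Crystallin genes of a family are similar in sequence and spots can share hybridisation, so the values of single members, Crygf and Cryge above all, are uncertain.

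The 4 named genes outside the crystallins that were at least 2-fold higher were Krt16, Saa3, Saa1 and Ceacam1. Krt16, a keratin of stressed and wound-activated epithelium, was 4.58-fold higher (log2 ratio 2.20 ± 0.04). The serum amyloid A genes encode acute-phase proteins. Saa3 was at least 4.17-fold higher (2.06 ± 0.20), a bound because the normal sample was not well above background on either array. With the deposited ratios its log2 ratio was 5.93. Saa1 was 3.94-fold higher (1.98 ± 0.15), with the normal sample above background on 1 of 2 arrays. Ceacam1, an adhesion molecule of epithelia and leukocytes, was at 1.25 ± 0.05 by its brighter probe, but its 2 probes differed in sign and their mean was 0.58. The remaining higher gene was an unnamed model.

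Of the 18 named genes at least 2-fold lower in the degenerative sample, 7 belong to the fixed retina list. Sag, the arrestin of rods, was at -2.10 ± 0.11 (4.29-fold lower). The phototransduction genes Gngt1 (-1.73 ± 0.19), Pdc (-1.64 ± 0.18), Pde6g (-1.55 ± 0.22), Pde6b (-1.44 ± 0.09) and Gnat1 (-1.44 ± 0.33) followed, with the outer segment membrane gene Rom1 at -1.70 ± 0.14. Rdh11, a retinol dehydrogenase, was at -1.55 ± 0.12. Vtn, which encodes the adhesive glycoprotein vitronectin, was at -1.79 ± 0.05 (3.47-fold lower). Scg5, a neuroendocrine chaperone, was at least 2.87-fold lower (-1.52 ± 0.35). Snap25, a component of the synaptic release machinery, had a bound of -1.58 ± 0.57. These are bounds because the degenerative sample was not well above background for either gene. Pcp2 was at least 2.66-fold lower (-1.41 ± 0.52) for the same reason. The other 5 were Pcp4, Guca1b, Unc119, Ckb and Reep6, between -1.38 and -1.26.

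Of the fixed retina list, 10 of 16 genes were measured, all 10 were below 0 on both arrays and 7 were at least 2-fold lower. The filter and the floor largely set the sign of Opn1sw, Rlbp1 and Rbp3, whose degenerative signal was not well above background. The list median was -1.50, against -0.13 to 0.13 for random lists. The list of iris, ciliary body and pigment cells had 3 measured genes, all lower: Dct at -0.87 ± 0.00, Tyrp1 at -0.74 ± 0.16 and Pmel at -0.62 ± 0.00, the melanin pathway genes. Its median of -0.74 lay below the random interval of -0.26 to 0.28. Without the filter on dim probes it was 0.05, the value that floored probes share, and lay inside its interval. Photoreceptor and pigment cell transcripts were thus measured in both samples labelled cornea, at a higher level in the normal one, and the lens transcripts at a higher level in the degenerative one.

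**Figure D2:**
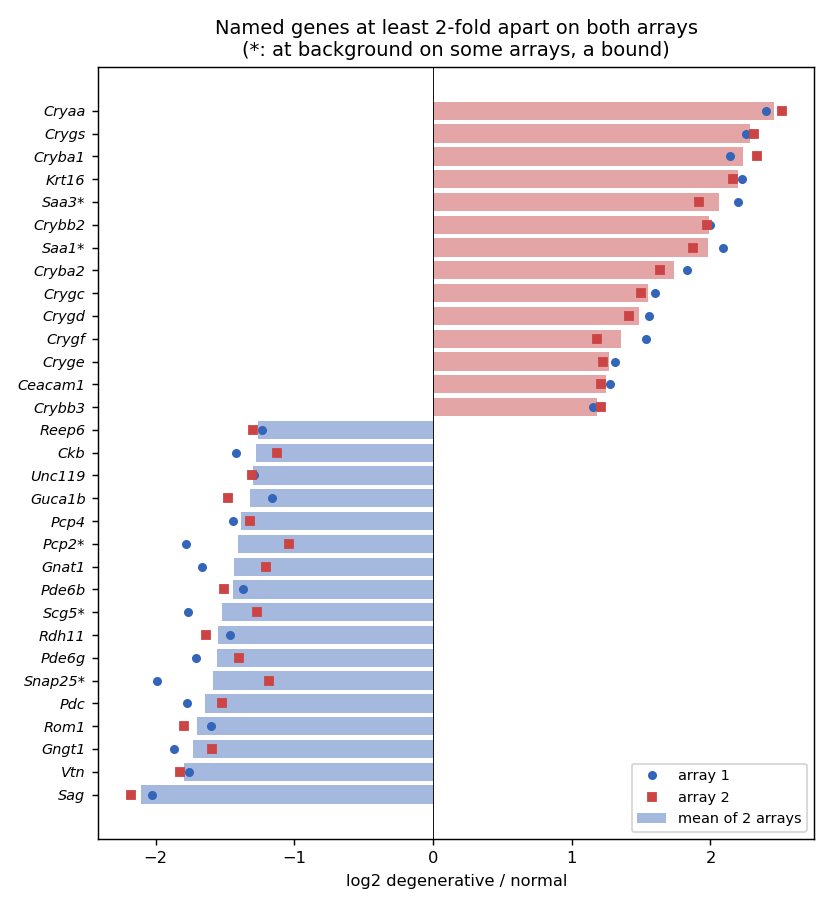
Mean log2 ratio of degenerative over normal (bars) for the named genes reported here that were at least 2-fold apart on both arrays, with array 1 (circles) and array 2 (squares); an asterisk marks genes at background on some arrays. Values run from 2.46 for Cryaa to -2.10 for Sag, and the arrays lie farthest apart for Snap25 (SD 0.57).

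Genes of the corneal epithelium were higher as a group, by far less than the lens genes. The 15 genes of the list with signal had a median of 0.18, against -0.11 to 0.13 for random lists, and 0 passed 2-fold. Of these, 4 were saturated in both RNAs, and the other 11 were above 0 on both arrays. The basal keratin Krt14 was highest at 0.73 ± 0.11 and was partly saturated. The gap junction gene Gjb2 was at 0.55 ± 0.19, and the epithelial transcription factors Klf4 and Trp63 were at 0.33 ± 0.01 and 0.30 ± 0.04. Krt12, the keratin specific to corneal epithelium, was saturated in both RNAs on both arrays and allowed no comparison; Krt5, Aldh3a1 and Tkt were saturated likewise. Without saturated genes the median was 0.23. Wound-activated keratinocyte genes had a median of 0.18 over 11 genes, against -0.13 to 0.15, and 0.38 without saturated genes. Beside Krt16, the laminin chains Lamb3 and Lama3 were at 0.57 ± 0.07 and 0.38 ± 0.06, and the integrin subunit Itgb1 at 0.49 ± 0.04.

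Genes of fibrotic matrix were higher, while keratocyte and endothelial genes went both ways. Whether an unequal share of other eye tissue, such as retina or pigment cells, contributed to the values in this paragraph was not tested. The fibrotic matrix list had a median of 0.38 over 7 measured genes, against -0.17 to 0.18, with 4 genes above 0 on both arrays and 2 below. Col3a1, a collagen of repair tissue, was at 0.84 ± 0.06, the matricellular gene Thbs1 at 0.45 ± 0.14, Tgfbi, whose human counterpart is mutated in stromal dystrophies, at 0.38 ± 0.10 and Sparc at 0.38 ± 0.09. This list fell inside the random interval with the brighter part of all probes (0.10) and with a threshold from blank spots alone (0.13). It also did so without the filter on dim probes (0.05), but that median is the value that floored probes share and says little about the list. Keratocyte genes had a median of -0.12 over 8 genes (interval -0.15 to 0.17), with Col6a1 at 0.73 ± 0.07 and Bgn at 0.41 ± 0.01 higher, and Ptgds at -0.73 ± 0.02 and Chst5 at -0.48 ± 0.21 lower. The deposited ratios placed this list below its interval, at -0.18. Corneal endothelium genes had a median of -0.13 over 6 genes (interval -0.18 to 0.18), from Cdh2 at -0.73 ± 0.10, partly below background, to Tjp1 at 0.44 ± 0.32. Col8a2, a collagen of Descemet's membrane, was at -0.34 ± 0.05, and Aqp1 at -0.31 ± 0.07. This list lay below its interval with a threshold from blank spots alone (-0.23). Matrix proteases and inhibitors had a median of 0.16 over 7 genes (interval -0.17 to 0.18), with Ctsb at 0.34 ± 0.11, Plau at 0.32 ± 0.15, Plat at 0.19 ± 0.10 and the inhibitor Timp3 at -0.52 ± 0.04. It lay above its interval with print-tip loess (0.18), the brighter part of all probes (0.15) and a threshold from blank spots alone (0.18).

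Proliferation and interferon response genes were higher by small amounts. Whether an unequal share of other eye tissue, such as retina, contributed to these values was not tested. The proliferation list had a median of 0.18 over 18 genes, against -0.10 to 0.11, with 14 genes above 0 on both arrays. Its largest values were those of the survival and mitosis gene Birc5 (0.43 ± 0.12), the topoisomerase Top2a (0.38 ± 0.06), the replication helicase subunit Mcm4 (0.33 ± 0.09) and Cdc20 (0.31 ± 0.18). The interferon response list had a median of 0.15 over 14 genes, against -0.11 to 0.13, with 10 above 0 on both arrays. Oas2, an antiviral enzyme, was at 0.48 ± 0.04, the transcription factor Stat2 at 0.37 ± 0.11, and Ifit1 at 0.38 ± 0.06. The interferon list lay inside its interval on array 2 alone.

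**Figure D3:**
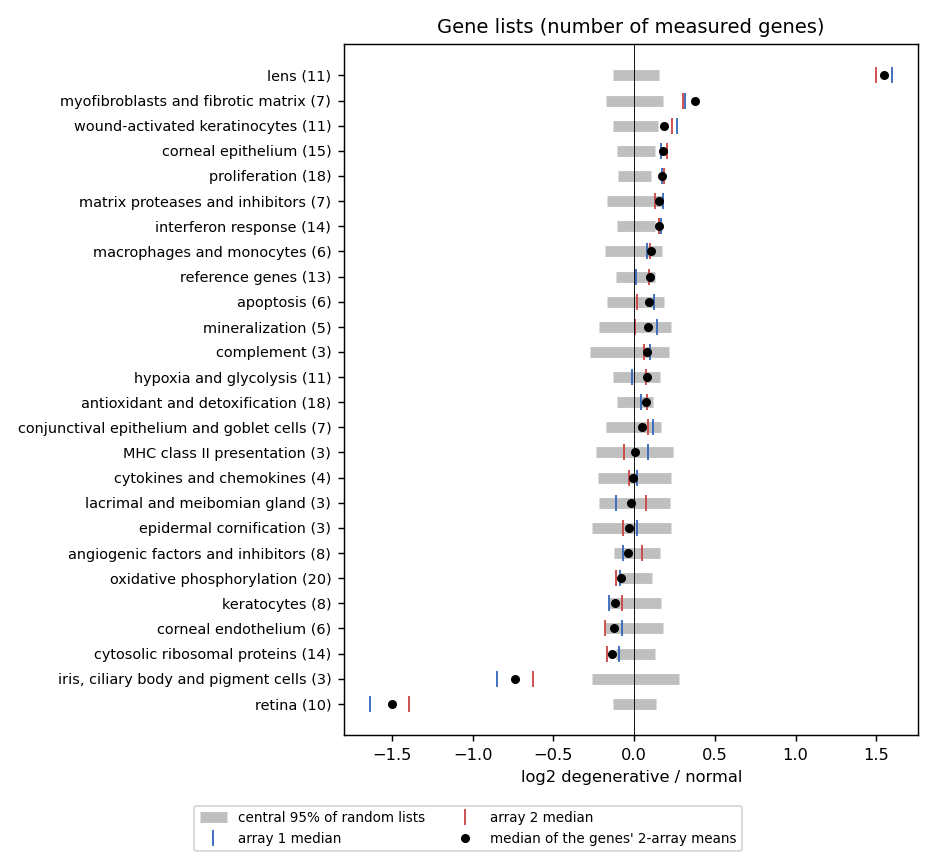
Median log2 ratio of degenerative over normal for the 26 gene lists with at least 3 measured genes (points), with the median on each array (ticks) and the central 95% of random lists of the same size and intensity (bars). The lens list lies at 1.55, the retina list at -1.50 and the pigment cell list at -0.74; other lists lie between -0.14 and 0.38.

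Of 26 lists with at least 3 measured genes, 6 lay above and 3 below the random interval. Cytosolic ribosomal protein genes lay below, with a median of -0.14 over 14 genes against -0.11 to 0.13. Rps14 was at -0.47 ± 0.15, Rplp1 at -0.26 ± 0.19, Rpl5 at -0.25 ± 0.10 and Rpl19 at -0.21 ± 0.02, and on array 1 alone the list lay inside its interval. Oxidative phosphorylation genes had a median of -0.08 over 20 genes (interval -0.09 to 0.11), with 12 below 0 on both arrays. Cox5b at -0.37 ± 0.03, partly below background, and Ndufa1 at -0.27 ± 0.13 were lowest. This list lay below its interval with median centring (-0.17) and on array 2 alone (-0.11). For the ribosomal and oxidative phosphorylation genes, a contribution from an unequal share of other eye tissue was not tested.

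Few genes of inflammatory cells exceeded the background threshold, which 5000 of the 14773 distinct names on the array passed. Among list genes with a probe, 6 of 22 passed for macrophages and monocytes and 4 of 32 for cytokines and chemokines. For neutrophils it was 1 of 16 and for T and NK cells 0 of 17. The macrophage and monocyte list had 6 measured genes and a median of 0.11 (interval -0.18 to 0.17), with Cd68 at 0.22 ± 0.11, Lyz1 at 0.21 ± 0.07 and Gpnmb, which pigment cells also express, at -0.46 ± 0.05. Cytokine and chemokine genes had a median of -0.00 over 4 genes, with Il17a at 0.16 ± 0.04 and Il1a at -0.08 ± 0.01. Genes of MHC class II presentation had a median of 0.00 over 3 genes, from H2-Aa at -0.04 ± 0.18 to Ciita at 0.04 ± 0.15. Complement genes had a median of 0.08 over 3 genes, with Serping1 at 0.32 ± 0.07 and Cd59a at -0.30 ± 0.11. These 4 lists lay inside their intervals. Lists with fewer than 3 measured genes gave no median to compare: Ly6g of the neutrophil list was at 0.12 ± 0.02, Kit of the mast cell list at 0.53 ± 0.06, and Sdc1 and Xbp1 of the B and plasma cell list at 0.41 ± 0.01 and 0.13 ± 0.07. Of the T and NK cell list, 0 genes were above background. These counts depended on the threshold: that from blank spots alone took in 26 cytokine and chemokine genes (median 0.18, inside the interval), 14 neutrophil and 16 T and NK cell genes.

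Angiogenic factors and inhibitors had a median of -0.04 over 8 genes (interval -0.12 to 0.16). The inhibitor Serpinf1 was at 0.43 ± 0.09 and Fgf1 had a bound of -0.40 ± 0.44. Of the vessel list, Pdpn was at 0.38 ± 0.13 and Angpt2 had a bound of -0.16 ± 0.16. For Fgf1 and Angpt2 the degenerative sample was not well above background on either array, so these are bounds. Their SD between arrays was at least as large as the mean, so the size of the bound is uncertain. Mineralization genes had a median of 0.08 over 5 genes (interval -0.22 to 0.23), with the phosphatase Alpl at 0.28 ± 0.05, Bmp6 at -0.14 ± 0.21 and the calcification inhibitor Mgp at 0.08 ± 0.08. Epidermal cornification genes had a median of -0.03 over 3 genes, with Sprr1a, a cornified envelope precursor, at 0.53 ± 0.08. Conjunctival and goblet cell genes had a median of 0.05 over 7 genes, with Krt13 at 0.36 ± 0.03 and Krt18 at -0.51 ± 0.08. Lacrimal and meibomian gland genes had a median of -0.02 over 3 genes, with Elovl4, an elongase also found in photoreceptors, at -0.70 ± 0.22. With normexp the gland list lay below its interval, at -0.25.

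Antioxidant and detoxification genes had a median of 0.07 over 18 genes, with the peroxiredoxin Prdx6 at 0.59 ± 0.11 and the superoxide dismutase Sod1 at -0.27 ± 0.15. Apoptosis genes had a median of 0.09 over 6 genes, from Cycs at -0.35 ± 0.12 to Trp53 at 0.25 ± 0.01. Hypoxia and glycolysis genes had a median of 0.08 over 11 genes, with Ldha at -0.51 ± 0.02 and Hk2 at 0.19 ± 0.19. The lists of this paragraph and the one before it with at least 3 genes lay inside their intervals. Of lists with 1 or 2 measured genes, Eno3 and Tnni2 of skeletal muscle were at -0.37 ± 0.08 and 0.00 ± 0.06, Hba-a1 of erythroid cells at -0.36 ± 0.12, S100b and Pmp22 of nerve at -0.26 ± 0.14 and -0.15 ± 0.22, and Car3 of adipocytes at -0.78 ± 0.08. Whether an unequal share of other eye tissue contributed to values such as those of Ldha, Cycs and Car3 was not tested.

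Reference genes had a median of 0.10 over 13 genes (interval -0.11 to 0.13). Actb was saturated in both RNAs. Gapdh was at -0.03 ± 0.19, with probes that differed in sign, and ranged from -0.16 to 0.11 over the settings tried. Mmp9, Vegfa and Spp1, which encode a gelatinase, an angiogenic factor and a mineral-binding matrix protein, were not well above background in either sample, and Kera, a proteoglycan core protein of the stroma, was not found by this name. This depended on the threshold: with that from blank spots alone, all 21 angiogenic list genes with a probe were measured, Vegfa included.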

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

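The choice to describe these spots was made after their values had been seen, and no test was run on them. They are control spots, outside the comparisons of the results, that carried signal above the blank spots. Spots named DMSO had a median Cy5 intensity of 1252 on array 1 and a median Cy3 intensity of 1647 on array 2, where blank spots were at -3 and -4.5.

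A further 8 kinds of control spot, named Y1 to Y8 with 48 spots each, had ratios that followed the RNA and not the dye. Mean log2 ratios of degenerative over normal were 0.89 ± 0.05 for Y1, 0.85 ± 0.09 for Y2, 0.87 ± 0.08 for Y3 and 0.36 ± 0.23 for Y4 (SD of the 2 arrays). They were 3.55 ± 0.14 for Y5, -1.90 ± 0.12 for Y6, 1.73 ± 0.07 for Y7 and -0.34 ± 0.19 for Y8. What these spots hold is not given in the sources used here, and the ratios are given as values only.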

How the results depend on the processing

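The thresholds from blank spots alone or with DMSO spots, normexp and the lists without saturated genes were chosen after seeing the data. Of the 15 higher and 20 lower genes, all 15 and 20 passed again with print-tip loess, the deposited ratios and normexp. They passed by construction with no filter, the brighter part of all probes, Aquantile scaling, which moved no ratio, and each array alone. Median centring and the DMSO threshold kept 15 and 19, and the mean of all probes of a gene 14 and 20. The counts grew with the blank threshold, to 122 probes higher and 190 lower (57 and 87 genes), with 689 probes in opposite directions and a correlation of -0.1304 between arrays over 30754 probes; floor and filter moved together there and the cause was not tested. Lower calls grew to 45 probes (34 genes) with the deposited ratios and 39 probes with normexp, with 18 probes higher under each, cause not tested. With each array alone, 25 to 36 probes were lower. At 1.5-fold, 50 probes were higher and 57 lower (35 and 40 genes), and at 3-fold 8 and 4 (8 and 4 genes), by construction. The correlation was 0.4784 with median centring, cause not tested, and 0.5621 with no filter, where floored probes carry no ratio of their own.

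The iris, ciliary body and pigment cell list turned from -0.74 to 0.0542 with no filter, because floored probes then made up most of it and share that value; the median of all probes on array 2 was then 0.12. Lists above and below their intervals numbered 5 to 7 and 2 to 4 over all settings. The lens and retina lists stayed outside in all of them, at 0.54 to 1.71 and -1.74 to -0.82. Of the values for named genes under alternatives, 382 moved by less than the SD between arrays, 38 moved by more and none changed sign among those called. Many of the 382 could not have moved by more. A single array always lies closer to the mean of the 2 arrays than the SD between them. No filter, the brighter part of all probes and Aquantile scaling reused the same ratios. The mean of all probes changes nothing for a gene with 1 probe. Signal over background was a limit, since 24.1% of gene probes exceeded it, and signals without background subtraction were not analysed.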

Other observations

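The dye tests on retina and crystallin genes and the tests of spread within the crystallins and the corneal epithelium genes were chosen after the results were seen. The inner retina list and the list of lens genes outside the crystallins were written after the medians of the fixed lists had been seen and before their own medians were computed.

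A further 15 named genes higher and 20 lower differed by at least 1.5-fold on both arrays without reaching 2-fold on both. Some of them had a mean of the 2 arrays beyond 2-fold. They were looked at after their values were seen, and the genes named here were picked without a fixed list or a test of any shared theme. Among the lower genes were the transcription factors Neurod1 (-1.26 ± 0.38, partly below background) and Nr2e3 (-0.85 ± 0.18), the photoreceptor transporter Abca4 (-1.07 ± 0.14) and the opsin Rgr of the pigment epithelium (-0.63 ± 0.05). Ttr, the thyroxine and retinol carrier that pigment epithelium makes, was at -0.62 ± 0.02 and the tight junction gene Cldn10 at -1.15 ± 0.22. Among the higher genes were Slc6a14, an amino acid transporter of epithelia (0.78 ± 0.12), Ripk4, a kinase of keratinocyte differentiation (0.61 ± 0.01), the fatty acid elongase Elovl5 (0.73 ± 0.08), the RNA helicases Ddx6 (0.99 ± 0.31) and Ddx46 (0.93 ± 0.08) and the transcriptional repressor Zbtb7a (0.86 ± 0.00).

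All 10 measured retina genes were lower in the degenerative sample, and a dye or array effect was argued against because 100% of them had the same sign on both arrays. For Opn1sw, Rlbp1 and Rbp3 the degenerative sample was not well above background, so the filter and the floor largely set their sign. The argument therefore rests on the 7 genes at least 2-fold lower. A candidate explanation is more retinal tissue in the normal sample: the inner retina list, which shares 0 genes with the fixed lists, had a median of -0.24, below the random bound of -0.16, as that explanation requires. The margin of 0.08 was smaller than the SD of 0.24 across the genes. Of the 32 genes 6 were measured, and 3 of the 6 were bounds. The filter and the floor largely set the sign of a bound, so these 3 add little. How many of the 32 the cornea also expresses was not tested. Lower expression of these genes within the degenerative cornea stays open as untested. A difference in dissection between eyes would be a way for more retinal tissue to enter the normal sample, and it was not tested either.

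All 12 measured crystallins were higher in the degenerative sample, although the filter and the floor largely set the sign of Crybb1. Its normal signal was not well above background on either array. A dye or array effect on the crystallins was argued against because 100% had the same sign on both arrays. Whether lens tissue of a fixed make-up was the only source of the signal on these spots stays open: the SD across the 11 crystallins above background in both samples was 8.64 times their median SD between arrays, and 6.06 times without Cryab, which other tissues also make. Spots that respond unequally, or shared hybridisation between family members, could give such a spread from 1 source. The rule written beforehand was that more lens tissue in the degenerative sample would raise the median of lens genes outside the crystallins above 0.20. Their median was 0.11, so the rule was not met. The shortfall of 0.09 was under the SD of 0.20 across the genes, a condition added after the result was seen. Only 5 of the 24 genes were measured, 7 of the 24 are in fixed lists, and Hspb1 is widely expressed. Lens tissue that raised these genes by less than the rule asks would not be seen, so the test cannot decide and the question stays open. Crystallin expression by corneal cells stays open as untested, with Mip, a gene of lens fibres, at 0.41 ± 0.01.

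The corneal epithelium genes were higher as a group, and a smaller share of other eye tissue in the degenerative sample could raise them all. The SD across the 8 genes with neither saturated nor background signal was 3.66 times their median SD between arrays, with values from 0.04 for Klf5 to 0.55 for Gjb2. That does not decide whether the shift was uniform, because spots can respond unequally. A shift that differs by gene, because other eye tissues express some of these genes, and a change in the epithelium itself stay open as untested.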
